A study of Homo sapiens with 2 samples.

How the data were processed

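Total RNA from K562 cells was sequenced after a TruSeq RNA library preparation (Illumina), per the labels' protocols, in 1 library of cells kept in bortezomib for 24 hours and 1 library of untreated cells. Groups were taken from the treatment label of each sample. The dose of bortezomib, the read length and the number of reads were not given in the sources used here.

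Reads were aligned with HISAT2 to GRCh37, per the submitters' processing notes, which give no version for the aligner. The program that made the expression values, its annotation and its use of strand were not given in the sources used here. The authors' deposited table holds FPKM per gene in both libraries, per the file headers. Columns of that table whose headers also say FPKM hold log2(FPKM + 1), since they equal it within 1e-06 in every row, and the deposited log2 fold change is the difference of these log2 columns, bortezomib minus untreated. The deposited fold change is the ratio of (FPKM + 1) of the libraries. The deposited p-value and q-value columns are 1 in all 10888 rows, so they carry no information and were not used. All 10888 rows are protein-coding genes, and the larger value of the libraries is at least 0.5 FPKM in every row, so genes below that in both libraries and genes of other classes were not analysed here. No column of sample values was left without a sample. Gene symbols, identifiers and GRCh37 positions were used as the table gives them. Of the symbols, 7 occur on more than 1 row, and the row with the higher mean stood for the symbol in gene lists.

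FPKM relates each gene to the total and to transcript length, so a large change in a few abundant genes shifts all others. The 10 most abundant genes held 13.1% of the summed FPKM in the bortezomib library and 16.7% in the untreated library. Other scalings by the median ratio, by a trimmed mean of log ratios and to the upper quartile divided the bortezomib values by log2 factors of -0.06, -0.02 and -0.06, which raised them slightly. Depth could not be recovered. In 203 genes with 1 exon, FPKM times length would fall on whole steps if whole reads had been counted. Only the lower values above 0 were used, and many steps were tried. The best step put 25.9% (bortezomib) and 21.5% (untreated) of them within 0.05 of a whole number. Evenly spread values would give 10% at any 1 step, and the best of many steps can give more. Precision per gene is therefore unknown, and no counting interval is given.

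The log2 ratio of (FPKM + 1), bortezomib over untreated, was computed for each gene. With 1 library per group no test is possible and no p-value was computed. Genes at 1 FPKM or more in at least one library were called higher or lower when this ratio was at least 1 in size, a rule of size fixed before the data were examined together with the gene lists, the naming rule and most of the alternatives. For each of 40 gene lists the median log2 ratio of members at 1 FPKM or more was set beside the medians of 10000 random lists of the same size, drawn with as many genes from each of 20 expression bins, for lists with at least 3 such members. This is a description of these libraries, since co-regulated genes are not independent. Genes named in the text are GATA2 and WT1, the 10 highest and 10 lowest ratios among genes with a symbol at 5 FPKM or more in at least one library, and up to 4 members of each list with the largest ratios in size; the others were picked out after their values were seen. Some of the genes this rule takes, and 1 of the lists with a test made on it, are not reported here. The rule left out the 23 genes at 5 FPKM or more whose names are clone identifiers.

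Of all genes, 8.37% overlap another listed gene on the same strand and 21.7% on the opposite strand. Reads of such genes may be divided or shared, and among the genes named in the text this holds on the same strand for GP1BB, BCL2L2, HBE1, RRM2, PSMB10, ENO2, ALDOC, MT-ATP6, MT-ATP8, TREX2, MAN2B1, CTSD, TOMM6, HBG2, TXNDC5, GABARAP, SEPT5, SENP3, EIF4A1, HSPE1, BLOC1S5, UBE2V1, TMEM189, AC120057.3 and the read-through models. On the opposite strand it holds for PSMC1, BCL2L2, ADRM1, DNAJB9, HSP90B1, DDIT3, SQSTM1, TNFRSF10B, MCM2, HIST2H4A, NOP16, KRT8, KRT18, SOCS1, TUBB2B, TUBA4A, TIGD1, GLA, NPC1, UCHL5, ALAS2, HBG2, TOMM6, HSPD1, HSPE1 and PMCH. GENCODE 29, which uses another genome build, served only for the length, GC content and exon number of transcripts, matched by Ensembl identifier for 98.7% of genes, and for the names of genes that overlap GATA2 and WT1. No position given in the text comes from it.

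The list method was tested on simulated data built on the 10888 genes with an assumed SD of 0.3. It placed 40 of 40 lists of 20 genes shifted by 0.5 outside the middle 95% of random lists, and 1 of 40 unshifted lists. The simulated genes varied independently, and the lists came from unchanged genes at 5 FPKM or more. Log2 ratios of the real libraries spread more widely, from -1.04 at the 5th percentile to 1.20 at the 95th, and real list members may be co-regulated. The simulated shares are therefore not error rates of the lists reported here. Alternatives were pseudocounts of 0.1 and 0.5, other filters on low values, 3 other scalings, a 3-fold rule, and removal of globin, ribosomal protein and mitochondrially encoded genes. After the data were seen, removal of overlapping gene models and subtraction of the median ratio of genes of like length (10 bins) and GC content (5 bins) were added, as was the addition of LAMP1 and LAMP2 to the lysosomal genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.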

Results

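The transcriptome of K562 cells was compared with and without bortezomib. K562 is an established human line that grows in suspension, was derived from chronic myeloid leukaemia in blast crisis, carries the BCR-ABL1 fusion and expresses erythroid and megakaryocytic genes. Bortezomib is a boronate drug that inhibits the chymotrypsin-like activity of the proteasome, the protease that degrades ubiquitin-tagged proteins. The data are 2 RNA sequencing libraries, 1 from cells kept in bortezomib for 24 hours and 1 from untreated cells, and the dose was not given in the sources used here. With 1 library per group there is no replicate error, so no difference below carries an SD, an interval or a test, and "higher" and "lower" describe these 2 libraries. The table lists 10888 protein-coding genes in FPKM, a fragment count scaled by transcript length and by the total of the library. The read depth of the libraries is unknown. The listed FPKM summed to 217060 in the bortezomib library and to 231457 in the untreated library, and the median gene stood at 5.99 and 5.85 FPKM.

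Bortezomib-treated cells differed from untreated cells by 2-fold or more at 1311 genes, with inducible stress genes among the 10 highest ratios and MYB among the 10 lowest of genes with a symbol at 5 FPKM or more. Among the 10141 genes at 1 FPKM or more in at least one library, 766 (7.55%) were higher and 545 (5.37%) were lower in the bortezomib library by a log2 ratio of at least 1 in size, and 8830 passed neither limit. The ratio is that of FPKM + 1, which understates the change of genes with low values, and a pseudocount of 0.1 in place of 1 gave 1183 higher and 856 lower genes. Simulated data with an assumed SD of 0.3 changed only genes at 1 FPKM or more in the untreated library. There the rule caught 86.8% of genes raised by a log2 ratio of 1.5 and 50% of those lowered by as much. The rule itself treats the libraries alike, and genes that rise from below 1 FPKM were not simulated. These shares thus do not bear on the split into higher and lower genes. The median log2 ratio was -0.03, with the 5th percentile at -1.04 and the 95th at 1.20. Across genes, which are not independent replicates, log2(FPKM + 1) of the libraries had a Pearson r of 0.913.

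Clone-named gene models are left out of the rankings here. The highest ratio among genes with a symbol at 5 FPKM or more belonged to CXCL8, the chemokine interleukin-8, at 95.4 FPKM with bortezomib against 0.572 without (log2 ratio 5.94, 61.3-fold on the FPKM + 1 scale; GRCh37 chromosome 4, 74606223 to 74609433). JUN, a subunit of the transcription factor AP-1, followed with 162 against 4.01 FPKM (5.03; chromosome 1, 59246460 to 59249999). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, stood at 54.1 against 0.993 FPKM (4.79; chromosome 6, 36644237 to 36655116). The rest of the 10 highest were OSGIN1 (4.24), the ubiquitin-binding autophagy receptor SQSTM1 (4.19, 242 against 12.3 FPKM), the extracellular chaperone gene CLU (4.16, 18.9 against 0.111 FPKM), the polyamine acetyltransferase SAT1 (4.16, 90.6 against 4.12 FPKM), the inducible chaperones HSPA1B (4.01) and HSPA1A (3.86), and the MAP kinase phosphatase DUSP1 (3.69).

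Among the 10 lowest ratios of these genes, MYB, FAM178B and SPN had values above 0 in both libraries and no overlap with another listed gene on the same strand. MYB, a transcription factor of haematopoietic progenitors, stood at 2.39 FPKM with bortezomib against 24.7 without (log2 ratio -2.93, 7.60-fold lower; chromosome 6, 135502453 to 135540311). FAM178B stood at 0.990 against 13.3 FPKM (-2.85) and SPN, the leukocyte surface sialoglycoprotein CD43, at 3.99 against 32.3 FPKM (-2.74). GP1BB, a subunit of the platelet von Willebrand factor receptor whose gene overlaps SEPT5, stood at 7.93 against 81.3 FPKM (-3.21). Of the remaining genes, BLOC1S5-TXNDC5, GAGE2C, TMEM189-UBE2V1, TIGD1 and TREX2 were listed at 0 in the bortezomib library and at 64.5, 42.1, 10.6, 6.16 and 5.86 FPKM in the untreated library. SENP3-EIF4A1, a read-through model over SENP3 and EIF4A1, stood at 6.84 against 54.8 FPKM. Values of such overlapping models, and of GAGE2C, which has near-identical copies, are uncertain, since the counting could divide shared reads between models.

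**Figure D1:**
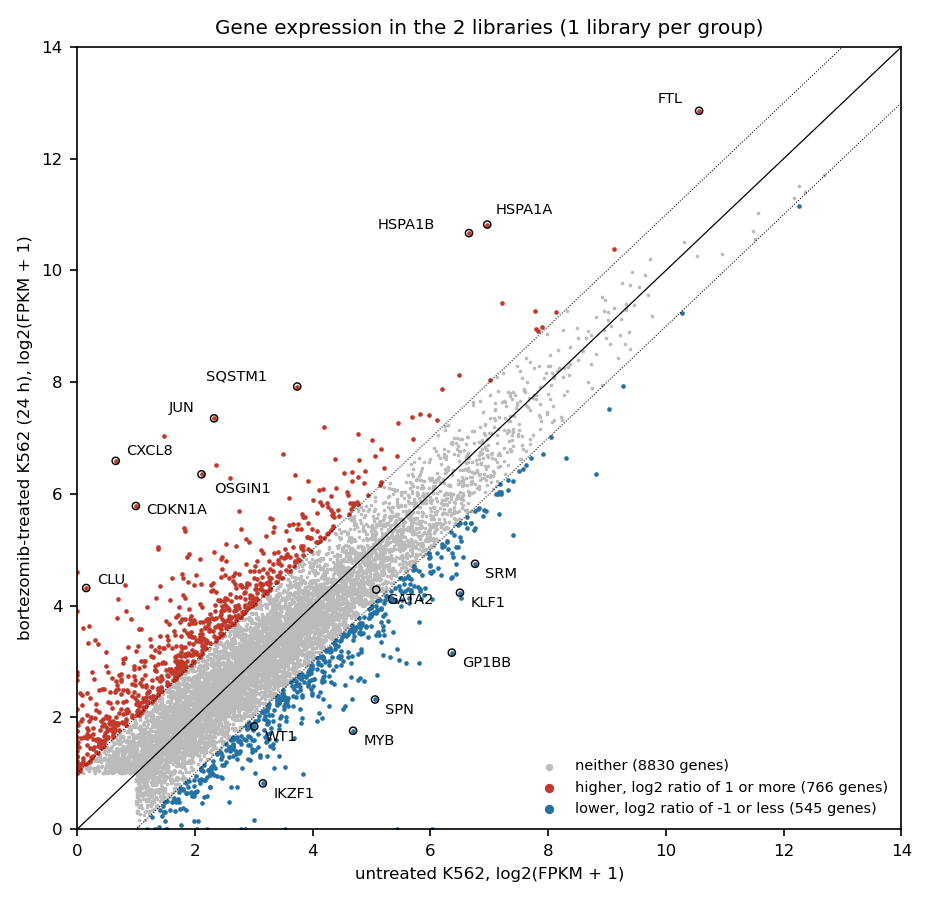
Each point is 1 of the 10141 genes at 1 FPKM or more in at least one library, with log2(FPKM + 1) of the untreated library on the horizontal axis and of the bortezomib library on the vertical axis; the solid line marks equal values and the dotted lines a log2 ratio of 1 and -1. The 766 higher genes (red) include CXCL8, JUN and CDKN1A, the 545 lower genes (blue) include MYB and WT1, and GATA2 lies inside the dotted lines.

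GATA2 and WT1, which the series title names as an axis in acute myeloid leukaemia, were both lower in the bortezomib library. GATA2, a zinc finger transcription factor of haematopoietic stem and progenitor cells, stood at 18.5 FPKM with bortezomib and 32.8 without, which is 56.5% of the untreated value (log2 ratio -0.79) and does not pass the 2-fold rule. WT1, the Wilms tumour zinc finger factor that many acute myeloid leukaemias express, stood at 2.58 and 7.03 FPKM, which is 36.6% of the untreated value (log2 ratio -1.17) and passes the rule. Of all genes at 1 FPKM or more, 10.1% had a lower ratio than GATA2 and 3.29% a lower ratio than WT1. GATA2 (ENSG00000179348.11_3) lies on the minus strand of GRCh37 chromosome 3, 128198270 to 128212028, and WT1 (ENSG00000184937.13_3) on the minus strand of chromosome 11, 32409321 to 32457176. In GENCODE 29 an antisense RNA gene overlaps each of them (GATA2-AS1 and WT1-AS), and use of strand in the counting was not given in the sources used here, so reads of these partners cannot be separated. With the trend over transcript length and GC content removed, GATA2 reached a log2 ratio of -1.002, just past the rule, and WT1 -1.22. That trend was weak across genes (Spearman correlation with the log2 ratio -0.02 for length and 0.09 for GC content), and its removal was chosen after the data were seen.

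The lower values of this pair stood among lower values of most haematopoietic transcription factors. Of the 19 measured members of that list, which holds GATA2 and WT1, 10 were lower past the rule, 2 were higher past it and 7 passed neither limit. The list median was -1.17, and 0 of 10000 random lists matched on expression had a median as low (their middle 95% ran from -0.41 to 0.28). The members with the largest ratios in size were MYB, the lymphoid factor IKZF1 (0.764 against 7.90 FPKM, -2.33), the erythroid factor KLF1 (17.8 against 89.6 FPKM, -2.27) and the corepressor CBFA2T3 (2.85 against 15.8 FPKM, -2.13). GATA1, the main erythroid GATA factor, stood at 51.2 against 119 FPKM (-1.20). The 2 higher members were the myeloid factors SPI1 (2.66 against 0.521 FPKM, 1.27) and CEBPA (1.82 against 0.376 FPKM, 1.04). TAL1 (19.8 against 17.0 FPKM) and RUNX1 (1.77 against 1.68 FPKM) differed by log2 ratios of 0.21 and 0.05. GATA1, SPI1, CEBPA, TAL1 and RUNX1 were picked out after their values were seen.

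**Figure D2:**
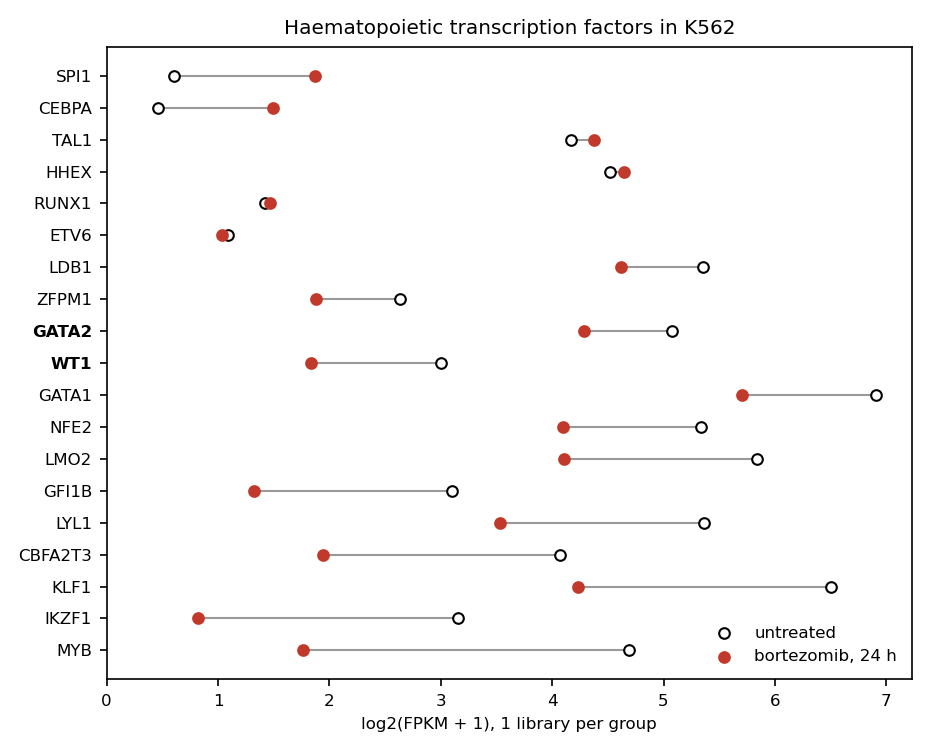
The horizontal axis gives log2(FPKM + 1) of the 19 measured haematopoietic transcription factors, with open circles for the untreated library and filled circles for the bortezomib library (1 library per group), and genes are ordered by their log2 ratio. The largest gap is that of MYB (-2.93), WT1 (-1.17) is the median member, and SPI1 (1.27) and CEBPA (1.04) are the members higher by 2-fold or more.

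Erythroid genes were lower as a group, with exceptions in both the haem pathway and the globins. Of 26 erythroid genes, 8 were lower and 1 was higher past the rule (median -0.46; 54 of 10000 random lists as low). TFRC, the transferrin receptor, stood at 21.8 against 81.7 FPKM (-1.86), the spectrin gene SPTB at 2.47 against 9.80 (-1.64) and TFR2 at 4.12 against 13.1 (-1.46). The higher member was ALAS2, the erythroid enzyme that starts haem synthesis, at 27.2 against 12.7 FPKM, a gene named after its value was seen. With the length and GC trend removed the erythroid median was -0.33, inside the range of its random lists. Of 9 globins 5 lay below 0 and the median was -0.79 (25 of 10000 random lists as low), with HBQ1 (-1.69), HBD (-1.60) and the embryonic HBZ (244 against 620 FPKM, -1.34) lower past the rule. The embryonic HBE1 was higher without passing it (270 against 139 FPKM, 0.96), although it overlaps HBG2 on the same strand and globin copies share sequence, so its value is uncertain. The fetal HBG1 (968 against 800 FPKM, 0.27) and HBG2 (615 against 492, 0.32), named after their values were seen, are the most abundant globins in the bortezomib library and lay above 0.

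Markers of the megakaryocytic and primitive compartments stayed inside their random ranges as groups. Of 6 megakaryocytic genes, GP1BB was lower and the collagen receptor GP6 higher (2.27 against 0.118 FPKM, 1.55), and the list median of 0.42 lay inside the random range. Of 5 primitive and leukaemia genes only LMO2, a partner of TAL1 in transcription complexes, passed the rule (16.3 against 56.4 FPKM, -1.73; list median -0.39, inside the range), and the 5 include BCR and ABL1, the partners of the fusion in this line. Among 10 STAT5 targets (median -0.33, inside the range) the cytokine signalling inhibitor SOCS1 was higher (29.4 against 2.72 FPKM, 3.03), and CCND2 (-1.35), BCL2L1 (-1.20) and PIM2 (-1.06) were lower.

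Genes of the proteasome, the target of the drug, were higher almost throughout. Most of the 34 genes in this list encode subunits, and it also holds an assembly factor and an activator. Of the 34, 33 had a log2 ratio above 0, 2 were higher past the 2-fold rule and 0 were lower past it. The median was 0.55 and 0 of 10000 random lists reached it. The ATPase subunits PSMC4 (159 against 68.1 FPKM, 1.21) and PSMC1 (73.5 against 34.9, 1.05) passed the rule, while the ubiquitin receptor ADRM1 (148 against 74.8, 0.98) and the catalytic-ring subunit PSMB7 (284 against 149, 0.93) came close to it. The 4 measured immunoproteasome genes, which encode interferon-inducible subunits and activators, had a median of -0.24, inside the random range, with PSMB10 at 7.90 against 15.1 FPKM (-0.85).

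Chaperone genes of the cytosol and of the endoplasmic reticulum were higher as groups. Of 24 genes in the cytosolic heat shock list, 16 lay above 0, 10 were higher and 0 lower past the rule (median 0.92; 0 of 10000 random lists reached it). HSPA1A and HSPA1B, which encode the inducible HSP70, were listed at 1809 against 124 and at 1627 against 99.8 FPKM. They are near-identical copies, so the division between them is uncertain. The small heat shock genes HSPB8 (11.1 against 0.0717 FPKM, 3.50) and CRYAB (12.8 against 0.598, 3.11) were the next highest members. Of members picked out after their values were seen, the cochaperone gene FKBP4 stood at 28.7 against 57.7 FPKM (-0.98), and HSPD1 (-0.34) and HSPE1 (-0.25), which the list holds although they encode mitochondrial chaperonins, lay below 0. Of 20 genes of the endoplasmic reticulum unfolded protein response, 19 lay above 0 and 8 were higher past the rule (median 0.89; 0 of 10000). HERPUD1, which acts in degradation of reticulum proteins, stood at 27.4 against 3.23 FPKM (2.75), the chaperone gene DNAJB9 at 27.4 against 4.46 (2.38), HSPA5, which encodes BiP, at 685 against 147 (2.21), and HSP90B1 at 618 against 217 (1.51).

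Target genes of the integrated stress response and of the oxidative stress factor NRF2 were higher as groups. Of 20 targets of ATF4 and CHOP, 16 lay above 0 and 4 below, 10 were higher and 0 lower past the rule (median 1.04; 0 of 10000 random lists reached it). DDIT3, which encodes CHOP, stood at 104 against 10.3 FPKM (3.21), ATF3 at 6.53 against 0.409 (2.42), CEBPB at 74.4 against 14.1 (2.32) and PPP1R15A, a phosphatase subunit that reverses eIF2alpha phosphorylation, at 133 against 26.4 (2.29). The cytosolic tRNA synthetases, another group that ATF4 can induce, were not higher: 1 of 18, VARS, was lower past the rule (28.4 against 82.5 FPKM, 2.84-fold), and their median of -0.45 lay inside the random range. Of 18 measured NRF2 targets, 16 lay above 0, 12 were higher and 0 lower past the rule (median 1.17; 0 of 10000). They were led by OSGIN1 (80.6 against 3.32 FPKM), PIR (22.8 against 2.44, 2.79), the ferritin light chain FTL (7419 against 1513, 2.29) and malic enzyme ME1 (68.2 against 20.1, 1.71). The 3 measured metallothioneins did not share this direction (median -0.67, inside the range), with MT1A at 0.829 against 3.19 FPKM (-1.20). With the length and GC trend removed their median was -0.75, below the range of their random lists.

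Autophagy genes were higher as a group, and genes of the ubiquitin and p97 system only in part. Of 19 autophagy genes, 3 were higher past the rule (median 0.41; 69 of 10000 random lists reached it): SQSTM1, the initiating kinase ULK1 (16.2 against 1.97 FPKM, 2.53) and the receptor OPTN (2.77-fold, 1.47). The lysosomal membrane gene LAMP1 stood at 10.6 against 20.9 FPKM (-0.91). Of 18 genes of the ubiquitin and p97 system, 6 were higher and 1 was lower, and the median of 0.16 lay inside the random range. The higher members included ZFAND2A, an arsenite-inducible zinc finger gene (40.5 against 5.84 FPKM, 2.60) and the p97 cofactor genes UFD1 (153 against 42.5, 1.82) and NPLOC4 (35.8 against 14.4, 1.26). The lower member, named after its value was seen, was UCHL5, a deubiquitinase of the proteasome (11.6 against 24.5, -1.02).

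Immediate early genes had the highest median of the lists fixed before the data were examined. Of 18 immediate early and AP-1 genes, all 18 lay above 0, 13 passed the rule and the median was 1.62 (0 of 10000 random lists reached it). After JUN and DUSP1 came IER5 (6.22-fold, 2.64) and FOSL1 (46.1 against 8.92, 2.25). Of 14 NF-kB targets, 7 were higher and 0 lower past the rule (median 1.08; 0 of 10000), among them the chemokines CXCL8, CXCL3 (8.47-fold, 3.08) and CXCL2 (7.25 against 0.716, 2.27) and the NF-kB subunit gene NFKB2 (13.1 against 2.80, 1.89). Of 9 interferon response genes, 4 were higher past the rule, IFI6 (14.8 against 3.36 FPKM, 1.86), IRF7 (3.85 against 0.587, 1.61), STAT2 (12.9 against 5.53, 1.09) and IFIT3 (1.87 against 0.358, 1.08). Their median of 0.48 lay inside the random range, and it passed the range at 0.67 when members needed 5 FPKM and at 0.84 with a pseudocount of 0.1.

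Members of the CDK inhibitor, pro-apoptotic and anti-apoptotic lists differed from one another. CDKN1A was the only 1 of 6 CDK inhibitor genes past the rule (list median 0.33, inside the range). Of 14 pro-apoptotic genes, 3 were higher past the rule, among them the TRAIL receptor gene TNFRSF10B (6.13 against 1.53 FPKM, 2.82-fold) and BBC3, which encodes PUMA (5.38 against 2.10, 1.04). The median of 0.54 was reached by 36 of 10000 random lists, but it was 0.26 and inside the range when members needed 5 FPKM or when all listed members entered. Of 7 anti-apoptotic genes (median -0.28, inside the range), BCL2L1, which encodes BCL-XL, was lower (13.6 against 32.6 FPKM, -1.20), as was BCL2L2 (0.376 against 3.34, -1.66), which overlaps a read-through model. MCL1 stood at 65.0 against 50.5 FPKM (0.36).

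Genes of ribosome biogenesis were lower while genes of the ribosome itself were slightly higher. Of 25 genes in the list of MYC targets and ribosome biogenesis, 12 were lower and 0 higher past the rule (median -0.97; 0 of 10000 random lists as low). SRM, the spermidine synthase gene, stood at 25.9 against 107 FPKM (-2.01), and the nucleolar genes NOP16 at 15.6 against 48.4 (-1.57), NOLC1 at 22.9 against 63.8 (-1.44) and RRP9 at 18.1 against 46.4 (-1.31). MYC, a member of the list picked out after its value was seen, was at 3.77 against 3.63 FPKM (0.04). Of 74 ribosomal protein genes, 56 lay above 0 and 0 passed the rule in either direction, with a median of 0.23 that 0 of 10000 random lists reached. RPL39 had the highest ratio (346 against 196 FPKM, 0.82) and RPS26 the lowest (119 against 207, -0.80). The 13 mitochondrially encoded genes all lay below 0 (median -0.86; 3 of 10000 random lists as low) and 3 of them passed the rule: MT-ND6 (184 against 525 FPKM, -1.51), MT-ATP8 (-1.12) and MT-ATP6 (-1.03).

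Most genes of the G2 and M phases were lower by less than 2-fold. Of 30 genes, 25 lay below 0 and 2 passed the rule, the kinase AURKA (16.6 against 39.7 FPKM, -1.21) and the proliferation marker MKI67 (8.80 against 19.7, -1.08), with a median of -0.49 (37 of 10000 random lists as low). TOP2A stood at 45.9 against 89.6 FPKM (-0.95) and UBE2C at 1.38 against 0.304 (0.87). The 30 genes of S phase had a median of -0.13, inside the range, with the ribonucleotide reductase gene RRM2 higher (37.9 against 17.9 FPKM, 1.04) and MCM6 (-0.96) and MCM2 (-0.96) just short of the limit on the lower side. The 15 homologous recombination genes had a median of -0.16, inside the range, and 0 passed the rule. The 17 replication-dependent histone genes split, 4 higher and 1 lower (median -0.02, inside the range), from HIST2H4A (21.9 against 4.40 FPKM, 2.08) to HIST1H2AC (-1.43, 2.69-fold lower), and histone copies share sequence.

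Of 20 glycolysis genes, 4 were lower and 1 was higher past the rule (median -0.46; 211 of 10000 random lists as low). Hexokinase 2, HK2, stood at 3.58 against 18.4 FPKM (-2.08), PGAM1 at 47.4 against 118 (-1.29), ALDOC at 5.01 against 12.1 (-1.12) and LDHA, named after its value was seen, at 71.5 against 145 (-1.01), while ENO2 stood at 5.38 against 2.12 (1.03). Both ALDOC and ENO2 overlap another listed model on the same strand. The 24 cholesterol synthesis genes had a median of -0.02, inside the range, and 2 were lower past the rule. Of 16 tubulin and actin cytoskeleton genes, 6 were higher and 0 lower past the rule (median 0.53; 5 of 10000 random lists reached it), among them TUBB2B (30.8 against 7.68 FPKM, 1.88), TUBB2A (81.6 against 22.0, 1.84), TUBA4A (42.8 against 11.7, 1.79) and thymosin beta-4, TMSB4X (171 against 55.6, 1.60).

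Markers of other cell types were used to see whether either library held other cells. Of 6 epithelial genes, 4 were higher and 1 was lower past the rule (median 1.07; 8 of 10000 random lists reached it). The higher ones were the keratin genes KRT19 (51.5 against 18.9 FPKM, 1.40), KRT18 (125 against 51.1, 1.28) and KRT8 (55.3 against 25.1, 1.11), which the untreated library also held, and CLDN4 (1.11 against 0.0349), named after its value was seen, while MUC1 was lower (1.09 against 3.67, -1.16). Of 4 monocyte and granulocyte genes (median -0.18, inside the range), CD68, a lysosomal protein gene, was higher (5.41 against 0.664 FPKM, 1.95) and LYZ stood at 31.7 against 28.3 FPKM (0.16). The lists for T cells, B cells, fibroblasts and endothelial cells had fewer than 3 measured members and gave no median. Of the 10 B cell, 9 fibroblast and 8 endothelial genes, 0 were among the listed genes. The list of nuclear-retained RNAs gave no median either, and only protein-coding genes are listed. The single measured T cell gene, NKG7, stood at 1.46 against 0.175 FPKM.

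**Figure D3:**
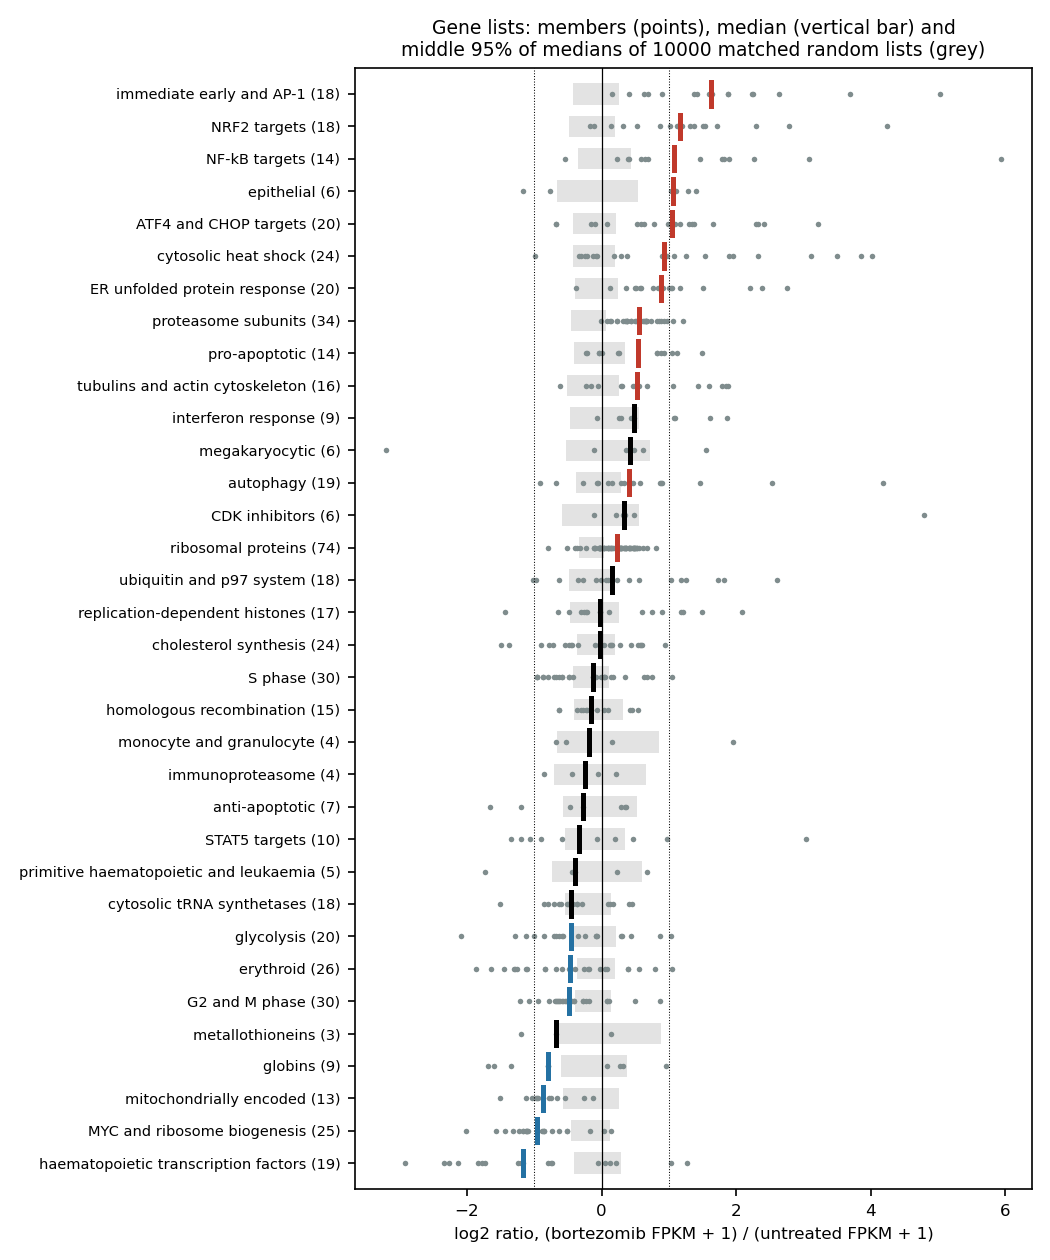
The horizontal axis gives the log2 ratio of FPKM + 1, bortezomib over untreated, for the measured members (points, number in brackets) of 34 gene lists with at least 3 of them; vertical bars are list medians, red above, blue below and black inside the grey range, which holds the middle 95% of medians of 10000 random lists matched on expression. The medians run from -1.17 for haematopoietic transcription factors to 1.62 for immediate early and AP-1 genes.

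Of all 35 such lists, 13 medians lay above the middle 95% of their random lists, 7 below and 15 inside. By chance 1.75 would lie outside if genes within a list varied independently, which co-regulated genes do not. The ranges describe how far a list stood from like genes of these 2 libraries, and they say nothing of how another culture would differ. No difference had a replicate check.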

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

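Of the alternatives in this section, those without overlapping gene models and with the length and GC trend removed were chosen after the data were seen, and the others before. The 3 other scalings each divided all bortezomib values by a single log2 factor, -0.06, -0.02 or -0.06. A list and its random lists shifted together there, so these values, counted below, could hardly change side. Of 277 alternative values of the 35 list medians, 271 stayed on the same side of the range of random lists and 0 medians outside it changed sign. The exceptions were the pro-apoptotic list median, which moved inside the range at 0.26 both with members at 5 FPKM or more and with all members in the table, the erythroid list median, inside at -0.33 with the length and GC trend removed, the metallothionein list median, below the range at -0.75 with that trend removed, and the interferon response list median, above the range at 0.84 with a pseudocount of 0.1 and at 0.67 with members at 5 FPKM or more. GATA2 passed the 2-fold rule at -1.002 only with the length and GC trend removed, and WT1 kept its side under all its alternatives. Of 22 alternative counts of genes past the rule, 18 stayed within 1.5 times the reported ones. A pseudocount of 0.1 gave 1183 higher and 856 lower genes, because a smaller pseudocount enlarges the ratios of genes with low values, and a 3-fold rule gave 242 and 99 by its construction. Of 896 alternative values of the 150 genes that the naming rule takes, 874 kept their side of the rule, 7 fell short of it and 15 newly passed it, and 0 of those past it changed sign. Apart from these constructions, the cause of the changes was not tested. Replicates are absent and depth is unknown, so neither leaving out a library nor a limit from read counts was possible.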

Other observations

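The tests of overlapping models, length and GC content and ZNF genes, and the comparison of symbol families, were chosen after the results were seen, while the test of unseen lysosomal members was set before their values were examined. Genes of the lysosome, of which the lists above held only a few, were higher as a group in the bortezomib library. A list of hydrolase and membrane protein genes was written after MAN2B1, SCPEP1, GLA, CTSL, CTSD and CD68 had been seen to be high, and these are its 6 highest members, so they are left out of the count. Of the 30 measured members not seen before, 7 were higher and 1 was lower past the 2-fold rule. Their median log2 ratio was 0.34, above the middle 95% of their random lists, which ended at 0.25, and reached by 40 of 10000. Picked out after their values were seen, PSAP (235 against 72.7 FPKM, 1.68) and NPC1 (9.85 against 2.94, 1.46) were higher and CTSH lower (2.44 against 6.96, -1.21). The list did not hold LAMP1 (-0.91) and LAMP2 (0.33) of the autophagy list. With both added afterwards to the 30, the median of the 32 genes was 0.32, again above its range, which ended at 0.24. Of the genes seen beforehand, GLA, which encodes alpha-galactosidase, stood at 97.2 against 19.8 FPKM (2.24) and the cathepsin gene CTSD at 96.0 against 26.5 (1.82).

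Families that share the start of their symbols showed further groups. Of 167 such families with at least 8 measured genes, 17 medians lay above and 7 below the middle 95% of random lists. By chance 8.35 would lie outside if genes of a family varied independently, which related genes may not do. That number counts both sides together, so it is no chance number for the 7 below alone. Some of the families outside, among them PSMB, PSMD, HSPA and RPL, hold genes of the lists above. The 3 other scalings moved all genes together by log2 factors of only -0.06, -0.02 and -0.06. That is too little to reverse a family median given here, so they are no check of direction. Most genes of mitochondrial protein import were lower by less than 2-fold, TIMM genes with a median of -0.55 (14 of 15 below 0, 1 past the rule) and TOMM genes with -0.71 (7 of 9 below 0). Both medians lay only just below their random ranges, which began at -0.52 for TIMM and -0.64 for TOMM. Among 167 families looked at, such small margins do not set these genes apart as a group. The 1 TOMM gene past the rule was TOMM6, whose gene overlaps another model, at 81.1 against 450 FPKM (-2.46). The 49 MRPL genes, which encode large subunit proteins of the mitochondrial ribosome, had a median of -0.42, with 3 lower past the rule and 0 higher. This was again only just below the random range, which began at -0.37. The 29 MRPS genes of the small subunit had a median of -0.24, inside their random range. The 12 GAGE genes, cancer-testis antigens of near-identical sequence, all lay below 0 (median -0.72). The 8 annexin genes all lay above 0 (median 0.73), with ANXA1 at 279 against 88.9 FPKM (1.64) and ANXA2 at 56.6 against 16.4 (1.73). The 51 HIST genes had a median of 0.50, with 14 higher and 1 lower past the rule, although the 17 histone genes of the fixed list had a median of -0.02. The 289 ZNF genes, most of which encode zinc finger transcription factors, had a median of 0.24, with 22 higher and 5 lower.

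The lower haematopoietic transcription factors were weighed against 2 explanations. A trend over transcript length and GC content is argued against as the whole cause, since with it removed the list median was -1.22, below the middle 95% of its random lists, which began at -0.36. A loss of transcription factor mRNAs in general would include the ZNF genes, whose median was 0.24. Their values argue only against a loss that reaches this family, and a loss among other transcription factors was not tested. An effect of bortezomib and a difference between cultures that has nothing to do with it remain open, because each group is 1 library.

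Of the genes at 5 FPKM or more in a library, 10 were listed at 0 in the other, 5 in each direction. A candidate explanation is that reads shared between overlapping gene models went to another model, since 6 of the 10 (60%) overlap another listed gene on the same strand, against 7.18% of the 6644 genes at that level. BLOC1S5-TXNDC5 went from 64.5 FPKM in the untreated library to 0 in the bortezomib library, while TXNDC5 inside it stood at 32.4 against 5.51 FPKM (2.36) but BLOC1S5, also inside it, at 6.36 against 8.96 (-0.44). TMEM189-UBE2V1 went from 10.6 FPKM to 0, while UBE2V1 stood at 46.2 against 33.1 (0.47) and TMEM189 at 2.72 against 3.86 (-0.39). Not every partner thus moved the opposite way. The clone-named AC120057.3 stood at 23.3 with bortezomib against 0, while GABARAP, which it overlaps, stood at 13.1 against 21.4 FPKM (-0.67). The other 4, TRPV3, PMCH, TIGD1 and GAGE2C, overlap none on the same strand. PMCH and TIGD1 overlap a listed gene on the opposite strand, and use of strand in the counting was not given. GAGE2C has near-identical copies. Shared reads may thus reach these 3 as well, and a change in expression of the 4 stays open.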
